A study of Sus scrofa with 6 samples.

How the data were processed

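Cortex from 6 male pigs, 3 wildtype and 3 with a maternally inherited UBE3A deletion, was frozen and its RNA extracted, per the labels' protocols. Libraries were made from RNA of integrity number above 6.1 with a stranded polyadenylated-RNA kit and sequenced as pairs of 150 bases on a NovaSeq 6000, per the labels' protocols. Groups were taken from the genotype in the labels. Replicates are separate animals by their animal numbers, and replicate numbers were given here in accession order, so they pair no animals. The leading part of the animal number (14 for replicate 1 of each group, 15 for the others) is unexplained in the labels and was used only as an alternative covariate.

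The aligner, the counting tool, the genome build, the annotation release and the use of strand in counting are not given in the sources used here. The authors deposited, per the file headers, exon read counts for each gene in each library, and whether these count reads or read pairs is not stated. These counts were whole numbers and entered every test as deposited, with blank cells read as 0. The authors also deposited RPKM values, which were used only to recover the gene length each value had been divided by, and TPM values, which were not tested. The authors' CPM column was treated as a score of their own scaling, because it sums to between 970329 and 1022538 per library, and was not tested. The authors' deposited table of the comparison gives a signed fold change, a p-value and an adjusted p-value per gene, and its test is not stated. Its 6 columns of group minimum, mean and maximum were not used.

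Each file held 28965 genes, of which 20288 were protein-coding, 6558 lncRNA and 2119 of other kinds, the last holding at most 0.37% of the reads of a library. Symbols came from the files for 16246 genes. Of the 12719 IDs without one, 777 matched the table of gene names and 0 more the RefSeq table, which left 11942 without a symbol. Total exon reads ranged from 19796762 to 28126173 per library. Within groups, chi-square per degree of freedom between libraries ranged from 15.1 to 55.7, so all 6 were counted as separate libraries.

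Genes were filtered with filterByExpr and scaled with TMM, and deletion was compared with wildtype by edgeR 4.0.16 (quasi-likelihood F test with robust dispersion, no covariate) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. Standard errors were taken as the absolute log2 fold change over the square root of F, with 95% intervals from its degrees of freedom. A total of 35 gene lists were fixed before the data were examined, as were the tests, the rule for named genes and most of the alternative settings. UBE3A was left out of each list, and the 34 lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, then with an estimated correlation and with fry, which tests whether genes move on balance in 1 direction without comparing them with other genes. Across those 34 lists, 14 passed with the preset correlation (5 higher and 9 lower), 0 with an estimated correlation (lowest adjusted p = 0.137) and 0 with fry (lowest adjusted p = 0.115). List means per library used log2(CPM + 0.5).

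Named genes were UBE3A and the tested genes of its imprinted domain, up to 15 rises and 15 falls of largest size past the adjusted threshold with a symbol, and up to 4 passing members per list, or the 2 of lowest p where none passed. Since fewer than 10 genes passed, the 20 genes of lowest p with a symbol were added, given as values. Some genes that this rule names are not reported here. Neighbours of UBE3A were to be taken within a window of its position. As no build is given, the 25 nearest tested genes on each side in the RefSeq order of assembly Sscrofa11.1 were used in place of it, a choice made after the data were seen.

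Alternatives were DESeq2's size factors, the DESeq2 1.42.0 Wald test, limma-voom with sample weights, no filter and a stricter filter (CPM of at least 1), the animal-number prefix, removal of mitochondrial and haemoglobin genes, a gene-length offset, a 1.5-fold minimum, and leaving out each library. Added after the data were seen were covariates for the oligodendrocyte marker score and for library size, an earlier edgeR dispersion method, and 10 neighbours on each side. A comparison of uniquely mapped reads was not run, since only total exon reads were used.

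The edgeR step was tested on simulated data for this comparison: 14300 genes, of which 200 were changed. It called 32% of genes changed 1.5-fold, 66% at 2-fold, 96% at 3-fold and 98% at 8-fold. It also made 17 false calls beside 146 true ones, more than the nominal share of 0.05. Changes under 1.5-fold are therefore mostly below what 3 animals per group detect at this depth. These rates probably overstate detection in the real comparison. The changed genes were drawn from those with more reads, and the adjusted threshold loosens as more genes pass, whereas 1 gene passed here. KLHL40, about 3-fold higher in the deletion group, did not pass (edgeR adjusted p = 0.16). On simulated counts with no effect camera called 1 of 34 lists; those counts were drawn gene by gene, with no correlation between genes.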

Results

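Gene expression was measured by bulk RNA sequencing of polyadenylated RNA from the cerebral cortex of 6 male pigs aged 140 days. Of these, 3 were wildtype and 3 carried a deletion of UBE3A inherited from the mother. UBE3A encodes a HECT-type ubiquitin ligase whose paternal copy is largely silent in neurons, and loss of its maternal copy causes Angelman syndrome in people. Each library came from a separate animal. The wildtype libraries held 23823287, 28126173 and 19796762 reads assigned to exons (replicates 1 to 3), and the deletion libraries held 28109327, 22297177 and 21802529. Of 28965 annotated genes, 14458 had enough reads to be tested. Levels are TMM-scaled CPM, given as mean ± SD with n = 3 per group, and differences are log2 fold changes of deletion over wildtype.

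UBE3A fell about 10-fold in the cortex of the deletion animals, from 91.0 ± 2.91 CPM (SD, n = 3) in wildtype to 9.07 ± 2.26 CPM (SD, n = 3). The 3 wildtype libraries held 2087, 2723 and 1823 UBE3A reads, and the 3 deletion libraries 330, 170 and 165. Relative to the wildtype mean, the deletion libraries stood at 12.8%, 8.6% and 8.5%, so every library matched its genotype label. The log2 fold change was -3.32 (SE 0.17, 95% interval -3.71 to -2.93), which left 10% of the wildtype level with an interval of 7.6% to 13.1%. edgeR's quasi-likelihood test gave it an adjusted p of 0.000452. Which part of the gene is deleted is not given in the sources used here, so the remaining reads cannot be assigned to either parental copy.

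The genes that share the imprinted domain of UBE3A mostly stayed near their wildtype levels. HERC2, another HECT ligase, measured 126 ± 9.34 CPM in wildtype and 105 ± 14.2 CPM in deletion cortex. Of the paternally expressed genes, MAGEL2 measured 43.3 ± 1.16 against 37.1 ± 5.12 CPM, with every deletion library below every wildtype library (edgeR adjusted p = 0.691), and NDN measured 90.3 ± 8.39 against 87.4 ± 14.7 CPM. For MKRN3, GABRA5, GABRG3, NIPA1, NIPA2 and TUBGCP5 the log2 fold changes were -0.18, 0.09, -0.32, 0.07, 0.10 and -0.22. None of the 10 tested members besides UBE3A passed edgeR's test over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there was 1, and DESeq2 called 0. As a set these genes had a median of -0.20 and did not pass camera (adjusted p = 0.118).

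**Figure D1:**
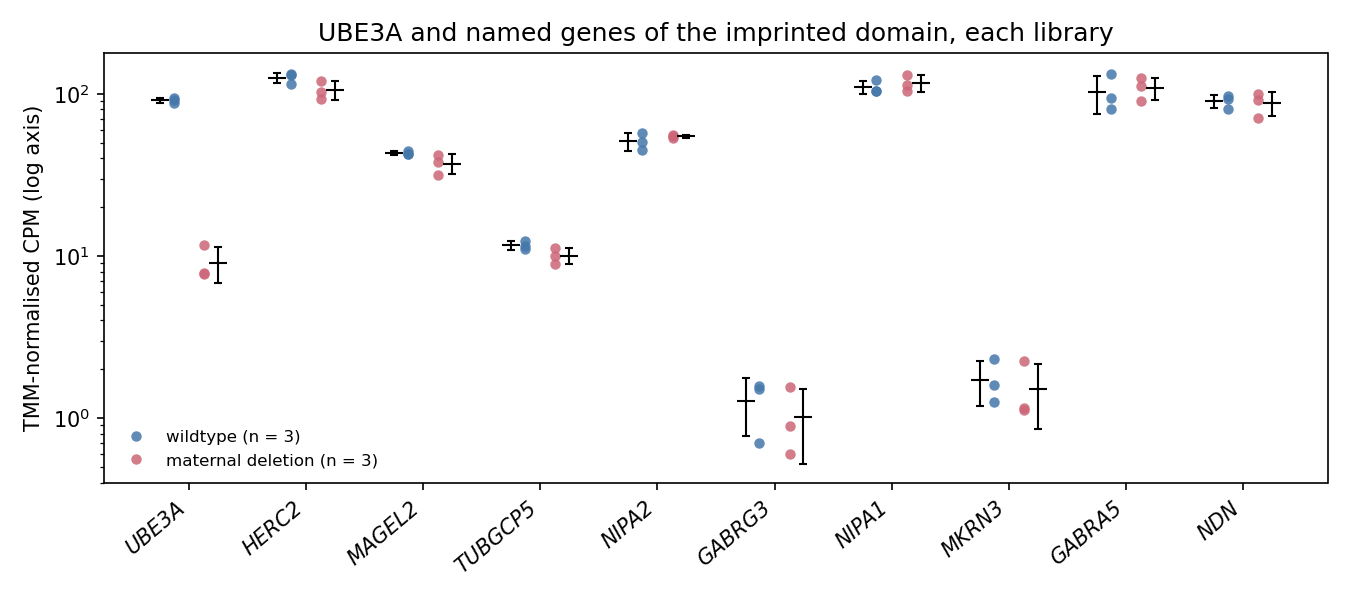
Each point is the TMM-scaled CPM of 1 library on a log axis for UBE3A and the genes of its imprinted domain named here, in wildtype (blue, n = 3) and maternal deletion (red, n = 3) cortex, with the mean and SD beside each group. UBE3A lies between 7.73 and 11.7 CPM in the deletion libraries and between 87.9 and 93.7 CPM in wildtype.

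Among the 50 nearest tested genes, 25 on each side of UBE3A in the gene order of assembly Sscrofa11.1, the median log2 fold change was -0.02. FAN1, a DNA repair nuclease, measured 23.9 ± 1.53 CPM in wildtype and 33.9 ± 1.44 CPM in deletion cortex (log2 fold change 0.50, SE 0.10, edgeR adjusted p = 0.683), with every deletion library above every wildtype library. A total of 6 neighbours, FAN1 included, had an unadjusted p under 0.05, among them MPHOSPH10 (0.37), NFATC1 (-0.71), IGF1R (-0.62) and KLF13 (-0.33), and none passed edgeR's adjustment. DESeq2 called 0 of them. As the only set in its family, it did not pass camera (adjusted p = 0.796), whose direction was upward while the median was below 0.

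UBE3A was the only gene that passed edgeR's test at an adjusted p of 0.05, so 0 genes were higher and 1 was lower in the deletion cortex. At an unadjusted p under 0.05 there were 1045 genes. The next in rank was KLHL40, a kelch-family protein best known from skeletal muscle, at 3.98 ± 0.81 CPM in wildtype and 12.005 ± 1.42 CPM in deletion cortex (log2 fold change 1.60, SE 0.19, edgeR adjusted p = 0.16). Every deletion library lay above every wildtype library for KLHL40, and its adjusted p ranged from 7.64e-09 with DESeq2 to 0.886 over the 17 other settings. It passed with DESeq2 and also without a filter on low counts (edgeR adjusted p = 0.0108).

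The remaining genes of lowest p are given as values, since each had an edgeR adjusted p of 0.683. PER1, a negative limb gene of the circadian clock that also responds to glucocorticoids, measured 192 ± 12.96 CPM in wildtype and 121 ± 16.7 CPM in deletion cortex. The collagen gene COL25A1 measured 20.0 ± 1.62 against 12.3 ± 0.74 CPM, and ULK1, a kinase that starts autophagy, 83.1 ± 4.51 against 60.5 ± 1.72 CPM. KDM6B, a histone H3 demethylase, stood at 28.5 ± 1.15 against 19.84 ± 0.36 CPM. Further genes with lower means in the deletion cortex were PADI1 (log2 fold change -0.84), ARHGAP33 (-0.47), PTPN9 (-0.47), MIDN (-0.46), IVD (-0.45), VSIR (-0.44), PDE4A (-0.42) and ADAM11 (-0.42). Higher means were found for the mitochondrial transcript ND6 (113 ± 21.6 against 188 ± 13.2 CPM) and for RND3 (21.1 ± 1.76 against 33.1 ± 3.87 CPM). They were also found for WSB1 (log2 fold change 0.62), FAN1 (0.50), the proteasome assembly factor POMP (0.48) and the annexin ANXA5 (0.46). In each of these 19 genes after UBE3A the libraries of the groups did not overlap, but they were picked for their low p, and 13.9% of all tested genes had groups apart where chance gives 10%. DESeq2 called 10 genes, 3 higher (KLHL40, ND6 and RND3) and 7 lower (UBE3A, PER1, COL25A1, SST and 3 genes without a symbol). limma-voom with sample weights called 1 gene.

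**Figure D2:**
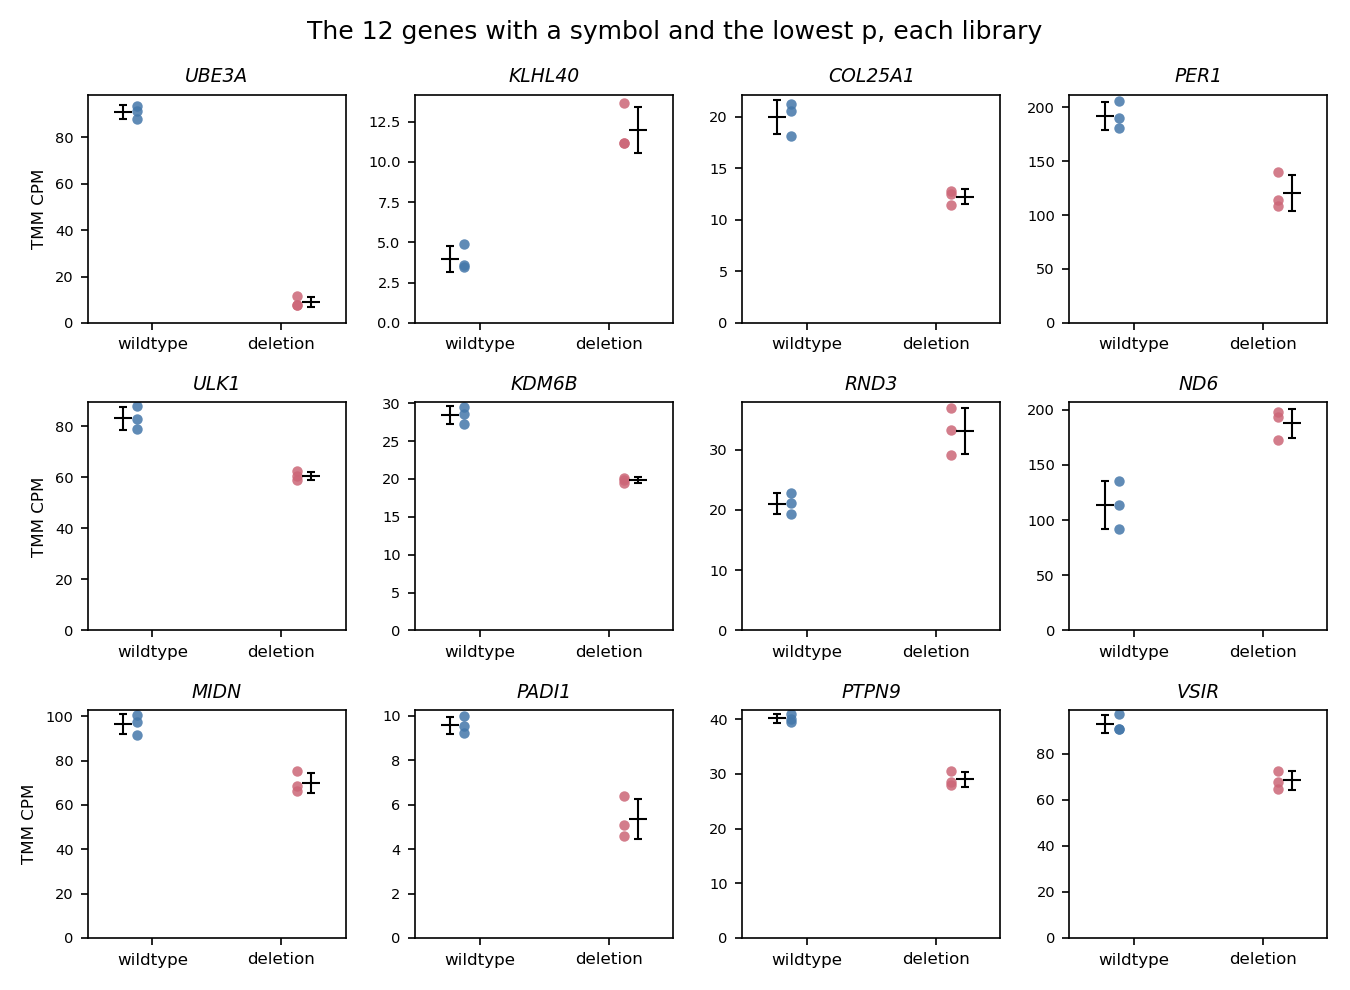
Each panel gives the TMM-scaled CPM of 1 gene on a linear axis from 0, with 1 point per library, for the 12 genes that have a symbol and the lowest p. Wildtype (n = 3) is blue and maternal deletion (n = 3) red, with mean and SD beside the points; of these genes UBE3A alone passed edgeR's adjusted test.

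The authors' deposited table lists 27 genes at an adjusted p under 0.05, 13 higher and 14 lower in the deletion group, where edgeR here called 1, UBE3A. In the authors' deposited table UBE3A has a fold change of -9.93 and KLHL40 one of 3.05. Of the 27 genes in the authors' deposited table, 23 were tested here, all 23 had the same direction, 22 had an unadjusted p under 0.05 and 19 had groups that did not overlap. The other 4 fell below the filter on low counts. The authors' genes had been picked for low p in the same libraries, so these counts give no independent support. The genes that follow were chosen after their values were seen. ND6, PER1, SST, ZBTB16 and FOSB are also among the 27. In each of them the groups did not overlap, and edgeR gave each an adjusted p of 0.683. In a pair of protein-coding genes without a symbol every deletion library lay below every wildtype library, while edgeR gave both an adjusted p of 0.683. One measured 609 ± 63.6 CPM in wildtype and 164, 22.7 and 20.4 CPM in deletion replicates 1 to 3 (log2 fold change -3.14, SE 0.81), and the other 14.0 ± 8.63 against 1.28 ± 1.12 CPM (-3.40, SE 0.72). In some of the others 1 library stood far from the rest. TTR, a choroid plexus transcript, stood at 17.2 CPM in deletion replicate 1 and between 0.619 and 1.51 CPM in the other 5 libraries. TH, which makes the dopamine precursor, stood at 27.2 CPM in deletion replicate 2 and at 4.69 and 5.38 CPM in the other deletion libraries, against 1.73 to 3.71 CPM in wildtype. GPNMB reached 22.4 CPM in wildtype replicate 1 and at most 1.55 CPM elsewhere.

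Gene lists of synaptic signalling and neuronal excitability were lower in the deletion cortex when tested with camera at its preset correlation of 0.01, with small shifts per gene. With an estimated correlation none of these 5 lists passed: the adjusted p was 0.345 for glutamate receptors and for channels, 0.137 for the presynaptic list, 0.384 for GABA genes and 0.575 for the postsynaptic list. Of 22 tested glutamate receptor genes 20 had negative log2 fold changes (median -0.18, camera adjusted p with the preset correlation 4.51e-05), as did 28 of 33 voltage-gated channel genes (median -0.25, 5.21e-06) and 20 of 23 genes of presynaptic vesicles and release (median -0.18, 7.72e-06). For GABA receptors and transporters these values were 13 of 19 (median -0.12, 0.0124) and for postsynaptic scaffold genes 17 of 22 (median -0.13, 0.0276). Examples are the kainate receptor subunit GRIK5 (126 ± 20.1 against 94.96 ± 7.45 CPM), the calcium channel CACNA1E (108 ± 11.7 against 78.5 ± 12.9 CPM), the vesicle protein SYNGR1 (695 ± 66.5 against 514 ± 58.6 CPM) and the GABA-B receptor subunit GABBR2 (631 ± 42.1 against 526 ± 10.1 CPM). GRM2, SYN3 and GABBR1 had log2 fold changes of -0.44, -0.96 and -0.25, while NRGN, a calmodulin-binding postsynaptic protein, stood at 0.54.

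No member of these 5 synaptic and channel lists passed edgeR's test over all genes or adjusted over the list alone. The mean of the presynaptic list separated the groups in all 6 libraries, whereas for the other 4 lists deletion replicate 1 lay inside the wildtype range. The postsynaptic list no longer passed camera without wildtype replicate 1 (adjusted p = 0.132), wildtype replicate 3 (0.236), deletion replicate 2 (0.132) or deletion replicate 3 (0.114), nor did the GABA list without wildtype replicate 1 (0.0603) or deletion replicate 3 (0.225). Mitochondrially encoded mRNAs took 13.1%, 11.2% and 13.6% of the reads in wildtype replicates 1 to 3 and 13.7%, 16.9% and 16.1% in the deletion replicates.

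Immediate early genes, which neurons switch on with activity, were lower as a list (19 of 26 negative, median -0.23, camera adjusted p = 0.000103), as were glucocorticoid-responsive genes (14 of 16 negative, median -0.29, camera adjusted p = 1.69e-05) and core clock genes (11 of 18 negative, median -0.11, camera adjusted p = 0.0183). With an estimated correlation the adjusted p was 0.384 for immediate early genes, 0.137 for glucocorticoid-responsive genes and 0.345 for clock genes. Adjusted over the list alone, 3 immediate early genes fell (FOSB, ARC and EGR3), as did PER1 and CRY2 of the clock list and PER1 of the glucocorticoid list, while 0 members passed over all genes with edgeR. FOSB measured 26.1 ± 0.95 against 14.5 ± 4.55 CPM, ARC 232 ± 51.7 against 150 ± 13.6 CPM and CRY2 141 ± 11.7 against 109 ± 2.00 CPM. The glucocorticoid-induced transcription factor ZBTB16 measured 60.6 ± 13.2 against 32.3 ± 11.6 CPM. Deletion replicate 2 had a mean of the immediate early list (0.16) inside the wildtype range, and without deletion replicate 3 that list had a camera adjusted p of 0.0554. The clock list no longer passed camera without wildtype replicate 1 (adjusted p = 0.0805), wildtype replicate 3 (0.0768), deletion replicate 1 (0.0536) or deletion replicate 3 (0.0554).

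Lists of ribosomal, mitochondrial, proteasomal and interferon-stimulated genes were higher in the deletion cortex by camera with the preset correlation. With an estimated correlation none of these 5 lists passed: the adjusted p was 0.384 for ribosomal proteins, 0.345 for mitochondrial transcripts, 0.636 for nuclear respiratory subunits, 0.446 for the proteasome and 0.345 for interferon-stimulated genes. Of 54 cytosolic ribosomal protein genes 53 had positive log2 fold changes (median 0.16), with RPS24 at 215 ± 11.6 against 284 ± 17.7 CPM and RPS18 at 136 ± 8.99 against 173 ± 7.08 CPM. Mitochondrially encoded transcripts had a median of 0.36 (12 of 13 positive), and COX2 stood at 9247 ± 1261 against 12763 ± 1226 CPM. Adjusted over the list alone 7 mitochondrial transcripts rose, and ATP8 fell (log2 fold change -0.48, SE 0.18). Over all genes 0 of the 13 passed edgeR. The estimated correlation between members was 0.726, so the 7 rises are not separate findings. Nuclear-encoded respiratory chain subunits (43 of 53 positive, median 0.11) included COX7C at 165 ± 13.8 against 205 ± 11.1 CPM and NDUFB1 at 14.9 ± 4.03 against 24.6 ± 5.03 CPM. Proteasome subunits (24 of 29 positive, median 0.14) included PSMA3 (log2 fold change 0.30) and PSMB1 (0.28). Interferon-stimulated genes had 21 of 26 positive values and a median of 0.39, with IFIT1 at 12.8 ± 2.08 against 19.7 ± 3.78 CPM and OAS2 at 14.0 ± 2.63 against 20.0 ± 1.40 CPM.

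With the preset correlation the camera adjusted p was 1.54e-13 for ribosomal proteins, 1.42e-10 for mitochondrial transcripts, 1.53e-05 for nuclear respiratory subunits, 8.51e-05 for the proteasome and 2.6e-07 for interferon-stimulated genes. The ribosomal and interferon lists separated the groups in all 6 libraries, while deletion replicate 1 lay inside the wildtype range for the other 3 lists. For the interferon list the separation was slight, with a mean of -0.020 in wildtype replicate 1 and -0.013 in deletion replicate 1. Without wildtype replicate 2 the nuclear respiratory list had a camera adjusted p of 0.0752. Reads of ND6, which lies on the opposite mitochondrial strand, and of ATP8, which overlaps ATP6, are uncertain because the use of strand in counting is not given in the sources used here.

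**Figure D3:**
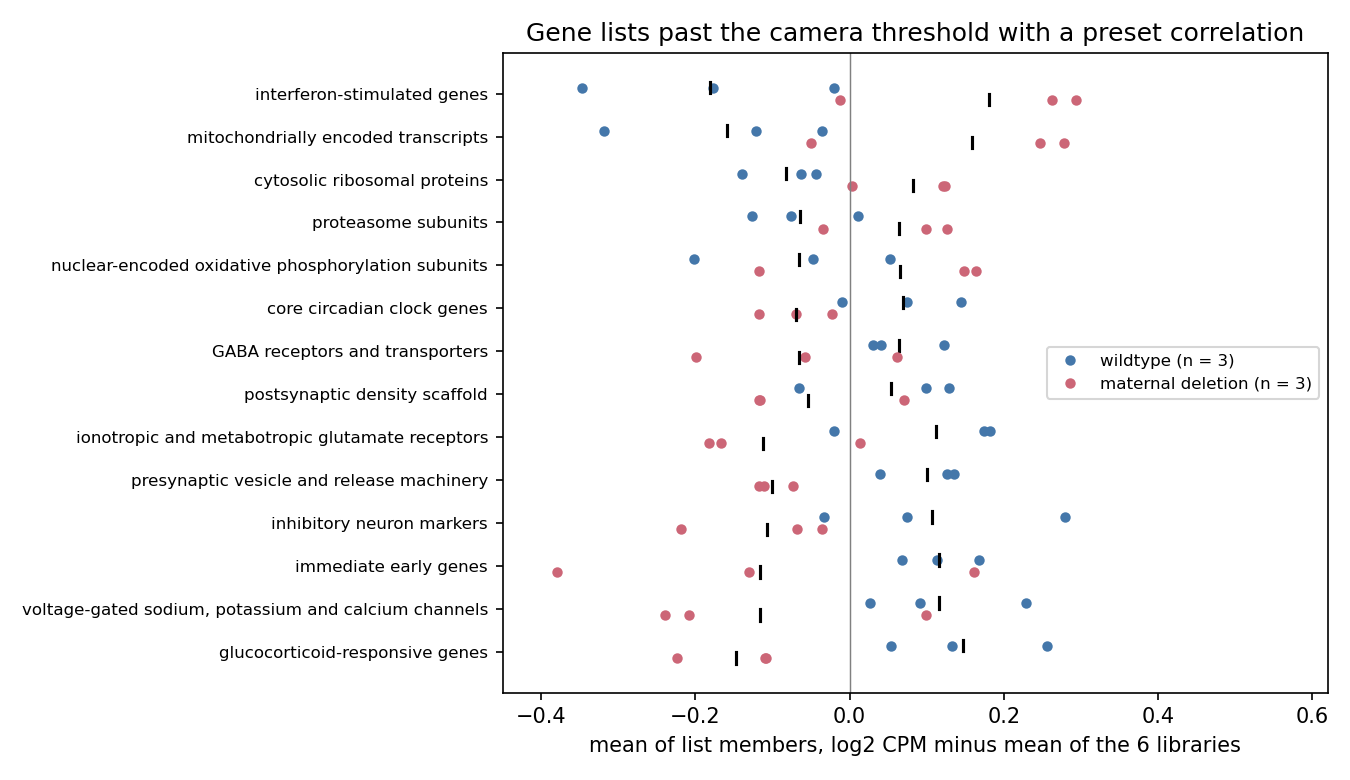
Each point is the mean over the members of a gene list in 1 library, as log2 CPM minus the mean of the 6 libraries, for the 14 lists past the camera threshold with a preset correlation; wildtype (n = 3) is blue, maternal deletion (n = 3) is red and black bars are group means. The groups do not overlap for 6 of the 14 lists, and none of the 14 passes with an estimated correlation. In the interferon, inhibitory neuron and clock lists the nearest wildtype and deletion libraries lie almost level.

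Of the cell type lists, inhibitory neuron markers were lower in the deletion cortex (16 of 19 negative, median -0.19, camera adjusted p = 0.000234), with an adjusted p = 0.384 with an estimated correlation. Adjusted over the list alone SST and GAD2 fell: the interneuron peptide SST measured 161 ± 3.58 CPM in wildtype and 96.8 ± 24.9 CPM in deletion cortex, and the GABA-synthesising enzyme GAD2 122 ± 19.8 and 87.7 ± 5.24 CPM. Over all genes neither passed edgeR (adjusted p = 0.683), and SST passed with DESeq2 (adjusted p = 0.0489). Without deletion replicate 1 the inhibitory list had a camera adjusted p of 0.0559. Excitatory neuron markers did not pass (camera adjusted p = 0.462). Astrocyte markers did not pass either (camera adjusted p = 0.263), with GFAP at 2177 ± 272 against 2790 ± 326 CPM and SOX9 at 44.7 ± 4.25 against 58.1 ± 1.81 CPM.

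Oligodendrocyte markers varied more between animals than between genotypes: their mean lay between -0.44 and 0.52 in the wildtype libraries and between -0.57 and 0.66 in the deletion libraries on the log2 scale (camera adjusted p = 0.0705). CNP measured 518 ± 201 against 683 ± 242 CPM and OPALIN 255 ± 95.1 against 344 ± 98.7 CPM. Leaving out wildtype replicate 2 or deletion replicate 2 moved this list past the camera threshold, with adjusted p of 1.87e-07 and 4.06e-08. Other lists that did not pass camera were precursor cells (adjusted p = 0.618, BCAS1 log2 fold change 0.75, CSPG4 -0.35), microglia (0.315, LAPTM5 -0.48, C1QC -0.39), endothelium (0.633, FLT1 -0.22, CLDN5 0.20) and mural cells (0.0705, KCNJ8 0.48, RGS5 0.22). Meningeal fibroblasts (0.331, OGN 0.34, SLC22A6 0.31), choroid plexus (0.0582, KCNJ13 0.91, TTR 2.58), striatal neurons (0.738, DRD1 0.51) and thalamic and hippocampal neurons (0.516, WFS1 -0.23, LHX2 -0.10) did not pass either. Some of these passed camera in other settings. Microglia (adjusted p = 1.89e-07) and precursor cells (0.00322) did so without deletion replicate 2, and astrocytes (0.0493) without deletion replicate 3. Mural cells (0.00603 and 0.00191) and meningeal fibroblasts (0.000411 and 0.00338) did so without deletion replicate 3 or wildtype replicate 1, and choroid plexus (0.0249 and 0.0171) without deletion replicate 2 or wildtype replicate 1. Choroid plexus also passed with the animal-number prefix as a covariate (0.0354) and with the stricter low-count filter (0.0315). Mural cells (0.000458) and meningeal fibroblasts (0.021) also passed with the oligodendrocyte score as a covariate, chosen after the data were seen. Only 2 blood genes had enough reads, HBB at 16.4 ± 22.3 against 22.8 ± 27.6 CPM and S100A8 at 0.51 ± 0.22 against 0.79 ± 0.28 CPM, so that list was not tested. The striatal list had a mean log2 fold change below 0 (-0.02) although its median (0.03) and its camera direction were upward.

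The remaining lists did not pass camera. Reported substrates and partners of UBE3A had a median of -0.04 (14 of 24 negative, camera adjusted p = 0.164), with ARC and the ubiquilin UBQLN2 (log2 fold change -0.28) the members of lowest p. HECT ligases had a median of -0.10 (camera adjusted p = 0.216), with HECTD4 at -0.36 and HERC6 at 0.36, and their camera adjusted p was 0.0174 without deletion replicate 1 and 0.0474 with the oligodendrocyte score as a covariate. Imprinted genes outside the domain had a median of -0.07 (camera adjusted p = 0.634; PEG3 -0.47, PEG10 -0.20). Neuropeptides and neurotrophins had a median of -0.11 (camera adjusted p = 0.131; SST, ADCYAP1 -0.42), SST fell when adjusted over the list alone, and the list passed without deletion replicate 3 (0.00346) and with the gene-length offset (0.0423). The perineuronal net list (camera adjusted p = 0.812; NCAN -0.22, SPOCK2 -0.18) had a median of 0.06 and a downward camera direction. Cholesterol synthesis genes (camera adjusted p = 0.346; MSMO1 0.33, SREBF2 -0.33) passed without wildtype replicate 2 (1.08e-05). Heat shock genes (0.812; DNAJB1 -0.24, HSP70.2 -0.46) and hypoxia-responsive genes (0.472; VEGFA 0.22, HK2 0.56) did not pass.

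The libraries resembled each other closely whatever their genotype. Correlations of log2 CPM across genes ranged from 0.9725, between wildtype replicate 2 and deletion replicate 2, to 0.9853, between deletion replicates 2 and 3. The first 3 principal components held 32.4%, 21.9% and 18.7% of the variance. On the first, wildtype replicates 1 to 3 lay at -8.52, -29.86 and 6.33 and deletion replicates 1 to 3 at -18.95, 33.50 and 17.48, so the groups overlapped.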

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

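Covariates for library size and oligodendrocyte score, the earlier edgeR dispersion and the neighbour sets were chosen after the data were seen. UBE3A stayed lower and past the threshold in all 17 other settings, with log2 fold changes from -3.551 to -3.218 and adjusted p from 1.62e-73 to 0.0144. The number of genes changed was 10 with DESeq2, 2 without a low-count filter (KLHL40 joins) and 2 with library size as a covariate (a gene without a symbol, log2 fold change -3.527, joins); leaving out 1 library gave 1 to 2, another gene without a symbol (-4.822) joining without deletion replicate 1. UBE3A was among the calls each time, and the cause of the added calls was not tested. The number of lists past camera was 0 with an estimated correlation and 0 with fry, against 14. The estimated correlation was above the preset one for 11 of those 14 lists, but not for the presynaptic, clock and glucocorticoid lists. A higher correlation therefore does not explain the calls those lists lost. On simulated counts with no correlation between genes, a list lowered 1.3-fold weakened too, from a camera adjusted p of 5.64e-22 to 0.0129. The estimated setting was thus stricter even without correlation, and how much each cause contributed was not tested. The number of lists was 12 to 17 when 1 library was left out. Over all lists and every setting but the estimated correlation and fry, 508 results stayed on their side of the threshold, 15 lost and 20 gained a call. Single named genes did so in 1533 results, gained a call in 7, and changed the sign of an uncalled value in 12. The camera direction of the genes flanking UBE3A turned downward with the oligodendrocyte score (median -0.014) and without deletion replicate 1, wildtype replicate 1 or wildtype replicate 3, with medians from -0.023 to 0.042 over the left-out libraries and p never under the threshold. The lowest correlation between libraries moved from 0.972 to 0.985 without a filter, and leaving out a library gave 0.972 to 0.977. No paired analysis was possible because the labels number no replicates and do not explain the animal-number prefix, which both groups share; with that prefix as a covariate UBE3A (-3.344) stayed the only gene called and 15 lists passed, the choroid plexus list joining the 14. Uniquely mapped reads and the 5 Mb and 2 Mb windows were not run.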

Other observations

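Within the inhibitory neuron list, the members did not all go the same way. RELN (log2 fold change -0.67, SE 0.19), LHX6 (-0.35, SE 0.14), SLC32A1 (-0.39, SE 0.18) and DLX2 (-0.63, SE 0.33) had every deletion library below every wildtype library, as SST and GAD2 did, whereas PVALB, a marker of fast-spiking cells, stood at 0.45 (SE 0.34). None passed edgeR over all genes, and these members were singled out after their values were seen. Among interferon-stimulated genes, RSAD2 (1.61, SE 0.50), IFI44 (0.66, SE 0.22) and IFIH1 (0.89, SE 0.31) were above wildtype in every deletion library, also without passing edgeR.

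Cell type lists differed between animals of the same genotype. On the log2 scale, the microglial mean ranged from -0.67 in deletion replicate 1 to 0.60 in deletion replicate 2, the meningeal mean from -0.60 in deletion replicate 3 to 0.66 in deletion replicate 2, and the mean of the 2 blood genes from -1.41 in wildtype replicate 2 to 0.88 in wildtype replicate 1.

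Of the tests below, the gene-length offset was planned before the data were seen and the others were chosen afterwards. The outcomes that would decide each test were written with its result known, except for library size. The 6 libraries can be split 10 ways into 3 against 3, too few for a share under 0.05. For genes changed, 4 of the 10 splits gave at least the real count of 1, and the highest other was 68, from wildtype replicates 1 and 3 with deletion replicate 2 against the rest. At an unadjusted p under 0.05 the real split gave 1045 genes and the highest other 2142, from wildtype replicates 1 and 2 with deletion replicate 1 against the rest. The split with 68 genes follows the oligodendrocyte score, which was below 0 in exactly those libraries, and so points to a structure of the samples other than genotype. For gene lists at the preset correlation, 1 of the 10 splits, the real one, gave as many as 14, and the highest other gave 13. By p the real split was not the most extreme. Its lowest unadjusted camera p was 4.52e-15, and in the other splits the lowest p ranged from 2.99e-08 to 1.18e-68.

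The lower neuronal and higher ribosomal, proteasomal and respiratory lists were set against 3 technical explanations. A gene-length trend, as unequal RNA integrity gives, was addressed by an offset fitted on the gene lengths recovered from RPKM. It moved the correlation of fold change with those lengths across genes from -0.117 to 0.004, as it was built to do. Under that offset 14 of the 14 called lists kept their call and direction. With the oligodendrocyte score as a covariate 12 of the 14 did, the postsynaptic list (adjusted p = 0.0888) and the clock list (0.0588) dropping out while HECT ligases, mural cells and meningeal fibroblasts joined, and the bound of 12 had been set with that count known. With library size as a covariate 14 of the 14 did. The count under the offset argues against a trend with the recovered lengths as the whole cause. Those lengths need not be transcript lengths (18872 bases for RPS24, 4497 for COX7C), so an effect of RNA integrity stays open. Library size and the oligodendrocyte score overlapped between the groups. The score was -0.425, 0.537 and -0.459 in wildtype replicates 1 to 3 and 0.666, -0.568 and 0.25 in deletion replicates 1 to 3. Adjusting for either could therefore remove few calls, so the counts under those covariates decide nothing. All of these counts rest on the preset correlation, with which arbitrary splits gave up to 13 lists. Genotype, RNA integrity, untested dissection differences and chance all stay open.

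Lower PER1, clock, glucocorticoid-responsive and immediate early genes may reflect the time of day at which tissue was taken, which the labels do not give. Clock genes of broadly opposite phase (ARNTL, CLOCK and NPAS2 against PER1, PER2, NR1D1, NR1D2, DBP, TEF, HLF and CIART) would then move apart. The first set minus the second differed by 0.142 between deletion and wildtype on the log2 scale (SE 0.225, exact two-sided permutation p = 0.7, the smallest possible being 0.1). That difference was 0.49 in deletion replicate 1, -0.17 and -0.11 in the other deletion libraries and -0.16, 0.08 and -0.14 in wildtype. The difference is smaller than its error, so it decides nothing about time of day, and it does not bear on handling before death. Time of day, handling before death and genotype therefore cannot be told apart here.

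FAN1 and 5 other neighbours of UBE3A at an unadjusted p under 0.05 could come from sequence linked to the deletion, or from a local effect of it. Of 1000 random runs of 50 neighbouring genes, 17.5% held at least 6 such genes, with a median of 4. This share settles neither explanation, and for FAN1 both stay open.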
